A study of Mus musculus with 2 samples.

How the data were processed

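Cochlear sensory epithelium of C57BL/6J mice aged 4 to 6 weeks was dissociated 2 days after noise and captured in 2 droplet libraries, 1 per group, each from 5 pooled ears: noise-only, and drug at 90 mg/ml before noise. The deposited matrices hold raw UMI counts per gene and barcode, with no normalization, per the file headers and by the values, which are all whole numbers. They were written by Cell Ranger 5.0.1 per the file header, and Cell Ranger 5.0, STAR, Seurat 3.2.2 and the builds mm10 and GRCm38 are listed per the submitters' processing notes, with no role given for each. The annotation release behind the counts is not given in the sources used here. The gene lists of both files were identical, with 32285 genes, of which 32158 identifiers were found in GENCODE M21, used for coordinates alone. The deposited barcode lists come with a smallest total of 500 UMIs in each file, and the filter that gave them is not stated; 111 barcode sequences occurred in both lists and were treated as separate cells.

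About 20000 recovered cells were stated, against 18545 noise-only and 21773 drug barcodes. Barcodes with at least 300 genes and 500 UMIs numbered 17667 and 20522, and those with at most 20% mitochondrial UMIs 17423 and 20133. Scrublet, as in scanpy 1.11.5 with an expected rate of 0.08, marked 1132 noise-only cells (6.50%, score threshold 0.227) and 2121 drug cells (10.5%, threshold 0.189), which were removed. The 16291 and 18012 cells left held 32843764 and 31792770 UMIs, so that 3 counts, the floor used against a sum of 0, stood at 0.0913 and 0.0944 CPM. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used, with edgeR 4.0.16 in R 4.3.3 for TMM factors.

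Both libraries were clustered together without batch integration, on 3000 variable genes chosen within library, 30 principal components, 15 neighbours and Leiden resolution 1. A cluster was named by markers of 28 cell types fixed before the data were examined. A type needed at least 3 markers, each at 2 times the level of the other cells and in at least 10% of the cluster's cells. Of such types, the one with the highest mean log2 fold of its markers was taken. It also needed a marker among the cluster's 10 leading genes, with no other type having more there. By this last rule cluster 11, with 5 Schwann markers detected in 423 noise-only and 562 drug cells, stayed outside the Schwann class. Of 43 clusters, 11 stayed unnamed, and the others gave 18 classes, each written as the type with "-like". The 17 classes with at least 100 cells in each library were compared, and the 6 with the most cells in their smaller library were the main classes.

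Each gene's UMIs were summed over the cells of a class and library and divided by the library's sum in that class to give CPM. The ratio of drug to noise-only CPM has an exact conditional binomial 95% interval, and log2 ratios use 0.5 UMI added to each sum. Genes needed 20 UMIs in the 2 sums together. Class shares have exact binomial intervals. With 1 library per group, no p-value, standard error or count of changed genes was derived from cells. For each of 25 gene lists fixed before the data were examined, of which 24 had enough members measured, the median log2 ratio of at least 5 measured members was set beside 10000 random lists of equal size matched on mean expression in 20 bins. This gave 386 list medians over all cells and the classes. About 1 in 20 would lie outside the central 95% by chance alone if the members of a list varied independently. Random lists were drawn gene by gene, so lists of genes that vary together can lie outside more often. Members were counted as higher or lower at log2 ratios of 0.32 and -0.32.

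Named genes were fixed by rule. Over all cells, the 10 genes in each direction were named whose interval bound nearest to 1 lay furthest from it, among genes with at least 50 UMIs in the larger sum; in each main class, 5 in each direction. Across classes, up to 10 genes in each direction with a ratio of at least 1.5 or at most 0.67 in 5 or more of the 6 main classes were named by median ratio. In a list, up to 2 members in each direction and Hdac1, Hdac2 and Hdac3 could be named. Mitochondrially encoded, ribosomal, haemoglobin, sex-linked marker, immunoglobulin and T cell receptor genes and models without a symbol were left out of naming. A further screen, chosen after the values were seen, named up to 5 genes per direction and class. It required, in the library where the gene was higher, a UMI in at least 5% of the class, a share at least 2 times that of the other cells, and at most 20% of the UMIs in 1 cell. Shares of cells with a UMI were also taken after thinning each cell to 1000 UMIs, which left out 7245 noise-only and 7798 drug cells.

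The ratio, interval, naming and list steps were tested on simulated data with 200 genes changed at known folds. Intervals covered the truth for 95.2% of unchanged genes over all cells, 95.8% in Schwann-like and 96.1% in macrophage-like cells. All 20 named genes were truly changed, and 5.1%, 4.8% and 3.8% of lists without change lay outside the central 95%. Intervals excluded 1 for 84.4%, 75.6% and 68.9% of genes at a true 1.5-fold difference and for 98.1%, 94.2% and 92.3% at a 2-fold one. The simulation holds counting error alone and no difference between pools. Each gene's sum was drawn as a single count without cells. Coverage and naming were therefore not tested for genes whose UMIs lie together in few cells.

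The alternatives tried were mitochondrial limits of 10% and none, minimums of 500 and 1000 genes, doublets kept, Leiden resolutions 0.5 and 2.0, and genes scaled within library before the principal components. Further ones were TMM and median of ratios factors, totals without mitochondrial, ribosomal and haemoglobin genes, a mean of each cell's CPM, thinning to 1000 UMIs, 5 UMIs added, list members of at least 1 or 100 UMIs, 5 bins, and the 6 main classes weighted equally. Settings added after the data were seen weighted clusters as in the noise-only library or left out cluster 15, clusters 35, 40 and 41, the top cell of each gene, or list members held by 1 cell or found in a smaller share of the class than of other cells. A cell barcode carries no mark of its ear, so mice were not compared. Reads were not used here. The values of a few genes that met the naming rules are not reported.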

Results

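Single-cell RNA was measured by droplet sequencing (10x Genomics 3′ v3.1 chemistry) in the cochlear sensory epithelium of C57BL/6J mice aged 4 to 6 weeks. All ears received an 8 to 16 kHz octave band of noise at 105 dB for 2 hours and were dissected 2 days later. 1 library pooled 5 ears given a drug at 90 mg/ml before the noise, and the other pooled the untreated contralateral ears of the same mice. The route of the drug is not given in the sources used here, so it is not known whether the drug also reached those ears. The series title abbreviates the drug as VPA, letters often used for valproic acid, an inhibitor of histone deacetylases, and the labels do not spell the name out. The question addressed was which cell types and which transcripts differed 2 days after noise between drug-treated and untreated ears.

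The noise-only file held 18545 barcodes and 38380393 UMIs, and the drug file 21773 barcodes and 39939170 UMIs; about 20000 recovered cells were stated. After filtering and removal of predicted doublets, 16291 noise-only and 18012 drug cells were compared. Median depth was 1115 UMIs per cell in the noise-only library and 1138 in the drug library. Mitochondrially encoded transcripts took a median of 4.73% of a barcode's UMIs in the noise-only file and 6.46% in the drug file. Xist, the transcript that coats the inactive X chromosome, stood at 672 CPM (UMIs scaled to a fixed library total) in the noise-only library (95% counting interval 664 to 680) and at 678 CPM in the drug library (670 to 686). The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 UMIs in both libraries, with upper limits of 0.0961 and 0.0924 CPM. With no Y-linked UMIs and ears of the same mice in both pools, these measures could not show a swap of the pools. Each group is 1 pooled library with no replicates. The intervals given with each ratio are 95% intervals for counting error alone, and no test between the groups was possible. Percentiles of gene lists are among 10000 random lists matched on expression and describe these 2 libraries. Those lists treat genes as independent, so an extreme percentile does not measure how unlikely a difference between single pools is. A list member is called higher or lower where its log2 ratio is at least 0.32 or at most -0.32, which is a description of size.

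Schwann or satellite glia-like cells, the myelinating and ensheathing cells of the nerve, were the most numerous named class in both libraries and the one whose share differed most among the large classes. They made up 40.6% of noise-only cells and 22.1% of drug cells, a ratio of 0.545 (0.524 to 0.567). Fibrocyte-like cells, which recycle potassium in the lateral wall, made up 9.16% and 13.7% (ratio 1.5, 1.40 to 1.60), endothelial-like cells 6.52% and 9.11% (1.40, 1.29 to 1.51), and pericyte-like cells 3.76% and 5.73% (1.52, 1.38 to 1.69). Cells with epithelial markers (other cochlear epithelium-like) stood at 6.41% and 7.32%, and macrophage-like cells at 4.22% and 4.52% with an interval of the ratio that included 1 (0.967 to 1.19). In the epithelium-like clusters 7 and 25, organ of Corti supporting cell was the second-ranked type, and it formed no class here. It did at clustering resolutions 0.5 (70 noise-only and 96 drug cells) and 2.0 (172 and 134). With at least 1000 genes per cell it held 201 and 187 cells. Hair cell-like cells numbered 103 and 161 (ratio 1.41, 1.10 to 1.83), and osteoblast or osteocyte-like cells made up 3.35% and 1.80% (0.537, 0.466 to 0.617).

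Because shares sum to the whole, the lower Schwann share lifts all others. Counted among the 9672 noise-only and 14023 drug cells outside the Schwann class, the ratio was 1.14 for fibrocyte-like, 1.16 for pericyte-like, 1.07 (0.986 to 1.15) for endothelial-like and 1.08 (0.837 to 1.39) for hair cell-like cells. It was 0.870 for epithelium-like, 0.817 for macrophage-like and 0.754 for neuron-like cells. Neuron-like cells had taken 2.61% of all noise-only cells and 2.59% of all drug cells. The osteoblast-like ratio was 0.409. With cells of at least 1000 genes alone, the endothelial ratio among all cells turned to 0.972, the epithelium ratio to 0.986 and the macrophage ratio to 0.818. The macrophage ratio was 0.804 at a clustering resolution of 0.5, where the class held 663 cells against 1501, and the fibrocyte ratio was 2.39 at a resolution of 2.0, with 1878 cells against 3966. Dissection and trypsin dissociation can set such shares, which are shares of captured cells and not of the tissue.

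**Figure D1:**
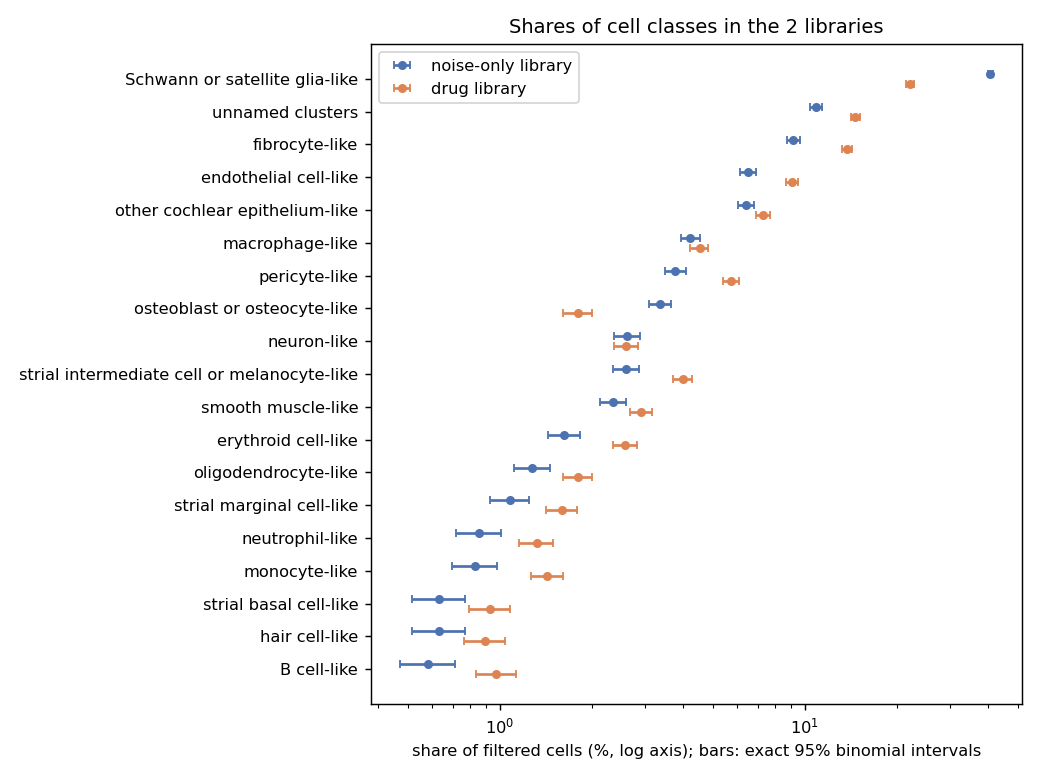
Share of analysed cells (percent, log axis) in each named cell class, noise-only against drug library; bars on the points are exact 95% binomial intervals for counting error in 1 library per group. The Schwann or satellite glia-like class stands at 40.6% and 22.1%, and the fibrocyte-like class stands at 9.16% and 13.7%.

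Over all cells, the transcripts furthest apart belonged to small groups of cells. Ttr, which encodes the thyroxine carrier transthyretin, was 0.0658-fold as high in the drug library (0.0645 to 0.0672), with 153728 UMIs in the noise-only library and 9796 in the drug library. Of its noise-only UMIs, 85.1% lay in cluster 37, an unnamed cluster of 55 noise-only and 61 drug cells with medians of 9312 and 2309 UMIs per cell. The tissue that this cluster came from was not determined, so its genes are not read as a response of cochlear cells. The same cluster held most noise-only UMIs of 6 further transcripts that were lower in the drug library, the prolactin receptor gene Prlr (0.0538), Prr32 (0.0383), Ins2 (0.0510), the serotonin receptor gene Htr2c (0.0894), the folate receptor gene Folr1 (0.151) and the bicarbonate transporter gene Slc4a5 (0.178). It also held most drug UMIs of the higher Tmem212 (40.7, 19.5 to 102) and Ccdc153 (24.1, 13.6 to 47.2). Slc4a11, a borate and proton transporter gene of cochlear fibrocytes, was 15.0-fold higher in the drug library (13.7 to 16.4), and Glycam1, a mucin-like ligand of L-selectin, was 109-fold higher (49.9 to 299, 6 and 634 UMIs). The fibrocyte-like cluster 15 held 84.0% of the Slc4a11 and 92.7% of the Glycam1 UMIs of the drug library. With clusters weighted as in the noise-only library, the Slc4a11 ratio was 4.42. All other ratios in this and the next paragraph carry no such weights, so they hold differences in cluster make-up as well.

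Tac1, the precursor of the neuropeptide substance P, was 18.9-fold higher (15.2 to 23.8), with 97.9% of its drug UMIs in the neuron-like cluster 13. Reg3g, an antibacterial lectin gene of mucosal epithelia, was 33.0-fold higher (27.8 to 39.5), Ly6k 24.0-fold higher and Serpina7 at least 17.9-fold higher against a floor of 3 counts (0 and 52 UMIs). In the drug library all lay mostly in the unnamed cluster 29, which also held 98.7% of the noise-only UMIs of the keratin gene Krt15, at a ratio of 0.185 (0.160 to 0.213). Mmp3, a matrix metalloproteinase gene, was 14.8-fold higher and Sln, the muscle peptide sarcolipin gene, 67.1-fold higher (11.6 to 2693, 1 and 65 UMIs). Retnla, a gene of alternatively activated macrophages, had 586 UMIs in the noise-only library and 1 in the drug library (ratio 0.00176, 4.46e-05 to 0.00986), and the adipokine gene Adipoq had a ratio of 0.151.

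If the drug inhibits histone deacetylases, the deacetylase genes and genes reported to rise with such inhibitors are of interest. The 11 measured HDAC genes had a median log2 ratio of -0.01, at percentile 65.8, and none was higher or lower by these bounds. Hdac1 stood at 0.989 (0.924 to 1.06), Hdac2 at 0.936 (0.873 to 1.003) and Hdac3 at 1.05 (0.968 to 1.14). Of the 14 genes reported to rise with inhibitors, 4 were higher, among them the chaperone genes Clu (1.72) and Hspa1b (1.55), and 4 lower, among them the actin-severing protein gene Gsn (0.742) and the cell cycle inhibitor gene Cdkn1a (0.764). Their median log2 ratio was -0.10 at percentile 15.7; it was 0.00 with cells of at least 1000 genes and 0.04 with the 6 main classes weighted equally. RNA levels 2 days after noise do not measure enzyme activity or histone acetylation.

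Myelin genes were lower over all cells, with a median log2 ratio of -0.45 and 8 of 10 lower, such as Pmp22 (0.653), the gene of a compact myelin protein. That median was -0.10 with the 6 main classes weighted equally, so that the lower Schwann share did not enter. Genes of cochlear ion transport and gap junctions had a median of 0.36, with 9 of 16 higher. That median carries no class weights, so it holds differences in cell make-up as well. The list members Slc4a11 and Slc4a10 were leading genes of the fibrocyte-like cluster 15, whose share ratio was 5.37. Mitochondrially encoded transcripts had a median of 0.41, with 10 of 11 higher, among them mt-Nd4l (1.40) and mt-Nd3 (1.38), subunits of complex I; the median was 0.25 with cells of at least 1000 genes. Cytokine and NF-kB target genes had a median of 0.10, which turned to -0.18 with cells of at least 1000 genes and to -0.03 with equal class weights. Extracellular matrix genes had a median of -0.17, which was -0.06 as a mean of each cell's CPM. Neither value carries class weights. The list members Col1a1, Col1a2, Col11a1 and Lum were leading genes of the osteoblast-like cluster 14, whose share ratio was 0.537. Interferon response genes stood at -0.04, at percentile 74.1.

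In Schwann or satellite glia-like cells, interferon response and MHC class I presentation genes were lower in the drug library. Of 22 interferon genes, 16 were lower and 1 was higher. The median log2 ratio was -0.62 where random lists ran from -0.14 to 0.05. Cxcl10, an interferon-induced chemokine gene, stood at 0.468 (0.402 to 0.544) and the GTPase gene Gbp2 at 0.370. Of 10 MHC class I genes, 6 were lower and none higher, with a median of -0.74. The immunoproteasome genes Psmb8 and Psmb9 stood at 0.425 (0.328 to 0.545) and 0.310. Among the myelin genes, Pmp22 was 0.874 and Mal 0.886, and the list's median of -0.09 lay at percentile 19.4.

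Mitochondrially encoded transcripts were higher in these cells, at a median log2 ratio of 0.61 with 11 of 11 higher, such as mt-Nd5 (1.61) and mt-Co1 (1.54), as they were in each of the other main classes. Immediate early genes had a median of -0.15, with Atf3, a stress-induced transcription factor gene, at 0.668, Klf2 at 1.22 and Nr4a1 at 1.16. Among the genes furthest apart, the extracellular matrix gene Matn2 stood at 0.339 (0.267 to 0.426), the phosphodiesterase gene Pde4b at 0.270, and the protease gene Klk8 at 0.230. Also lower were the interferon-inducible GTPase gene Ifi47 at 0.0413 (89 and 2 UMIs) and Ttr at 0.0869. The higher ones were Slc1a2, a glutamate transporter gene (4.65), Aldoc, a glycolytic aldolase gene (3.14), Otos (2.81), Lgals3 (2.78, with 24.3% of the drug UMIs in 1 cell) and S100a9 (3.05, with 98.5% of its drug UMIs over all cells in the neutrophil-like cluster 28). These 5, like Pde4b, Klk8, Ifi47 and Ttr, were found in a smaller share of Schwann-like cells than of other cells in both libraries.

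Genes were also screened, by a rule chosen after the values were seen, for a UMI in at least 5% of the cells of a class and in at least 2 times the share of other cells. In Schwann-like cells it named the proton channel gene Otop1 (1.46, 1.29 to 1.64), the metallothionein gene Mt3 (1.253), the semaphorin gene Sema5a (1.28) and Fabp7 (1.31) among the higher genes. Fabp7 turned to 0.834 with cells of at least 500 genes and lay below 1 in 4 further settings. The screen named Scn7a, a sodium channel gene of non-myelinating glia (0.460), Sbspon (0.67), the creatine synthesis gene Gatm (0.776, 0.740 to 0.813) and the lipid transporter gene Abca8a (0.711) as lower. Scn7a, Abca8a, Fabp7 and Matn2 were the leading genes of cluster 3, which had 1104 noise-only and 502 drug cells, and with clusters weighted as in the noise-only library Scn7a stood at 0.598 and Matn2 at 0.419. Gatm had a UMI in 52.2% of noise-only and 43.4% of drug Schwann-like cells against 19.0% and 14.4% of other cells, at median depths of 766 and 693 UMIs in the class. With cells of at least 1000 genes, which left 227 noise-only and 99 drug Schwann-like cells, the interferon median was -0.20, the MHC class I median -0.09, the immediate early median 0.10, Matn2 1.01, Otos 0.919, Ifi47 2.25 and Ttr 1.06.

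In fibrocyte-like cells, cochlear ion transport genes were higher in the drug library, and the medians of cytokine, complement, interferon and matrix genes were lower, together with a different make-up of the class. Of 13 ion transport genes, 8 were higher and 2 lower, at a median log2 ratio of 1.13; it was 0.13 over the 7 left without members with over 20% of their UMIs in 1 cell or found in a smaller share of the class than of other cells. Slc4a11 was 11.6-fold higher (10.4 to 12.8) and the sodium bicarbonate transporter gene Slc4a10 14.9-fold higher (10.95 to 20.9), while the tight junction gene Cldn11 stood at 0.788. Slc4a11 had a UMI in 7.17% of noise-only and 29.2% of drug fibrocyte-like cells, against 0.439% and 2.24% of the other cells. Cluster 15, which held most drug UMIs of Slc4a11, had 121 noise-only and 719 drug cells, cluster 2 had 953 and 1045, and cluster 10 had 419 and 709. With the clusters weighted as in the noise-only library, the ion transport median was 0.33, Slc4a11 was 3.36-fold higher and Slc4a10 3.93-fold higher; without cluster 15 the median was 0.20, Slc4a11 stood at 1.91 and Slc4a10 turned to 0.701.

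Cytokine and NF-kB target genes had a median log2 ratio of -0.61 in fibrocyte-like cells (10 of 17 lower, 5 higher), with the iron-sequestering lipocalin gene Lcn2 at 0.262 and the chemokine gene Ccl7 at 0.469. Complement genes had a median of -0.50 (6 of 10 lower), with Cfb at 0.375 and C4b at 0.560. Interferon genes had a median of -0.30 (10 of 22 lower), with Ifit1 at 0.473 (0.432 to 0.517), Rsad2 at 0.493 and Ifi27l2a at 2.25. Extracellular matrix genes had a median of -0.37 (14 of 21 lower), with the proteoglycan genes Dcn at 0.532 and Lum at 0.583 and the cochlin gene Coch at 1.22. Immediate early genes had a median of -0.34. With the noise-only cluster weights these medians were -0.14 for cytokines, -0.10 for complement, -0.17 for interferon, -0.01 for matrix and 0.03 for immediate early genes.

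The fixed rule further named Saa1, an acute-phase protein gene (0.171, with 57.4% of the drug UMIs in 1 cell, and 0.0797 without the top cells), Sostdc1 (0.299), the surface antigen gene Ly6a (0.421) and Ttr (0.0218) as lower in fibrocyte-like cells. It named Glycam1 (143, 48.6 to 693, 3 and 588 UMIs), Veph1 (15.5) and Wfdc18, with 95.2% of its drug UMIs in 1 cell, as higher. Most drug UMIs of Glycam1 lay in cluster 15, which had 121 noise-only and 719 drug cells. The ratios of Glycam1 and Veph1 are without cluster weights, so they hold that difference in make-up. Sostdc1, Wfdc18 and Ttr had a UMI in a smaller share of fibrocyte-like than of other cells in both libraries. The screen chosen after the values were seen added the phosphatase inhibitor gene Ppp1r1a (5.97), the glucocorticoid-activating enzyme gene Hsd11b1 (7.09) and the inositol transporter gene Slc5a3 (4.63) as higher. It added the chemokine genes Cxcl12 (0.437) and Ccl11 (0.394), the bone sialoprotein gene Ibsp (0.429) and Tgfbi (0.461) as lower. With the noise-only cluster weights these became 1.78 for Ppp1r1a, 2.40 for Hsd11b1, 1.87 for Slc5a3, 0.665 for Cxcl12, 0.612 for Ccl11, 0.685 for Ibsp and 0.703 for Tgfbi. Over all cells, 91.9% of the noise-only Ibsp UMIs lay in the osteoblast-like cluster 14. At a clustering resolution of 2.0, among fewer cells of the class, Lcn2 turned to 5.62.

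In endothelial-like cells, interferon response genes were slightly higher in the drug library, opposite to the Schwann-like cells; the difference between the classes was not tested. The median log2 ratio of 22 interferon genes was 0.17, above all 10000 random lists, with 2 higher and none lower. Ifi27l2a stood at 1.40 and Ifit3 at 1.28 (1.12 to 1.46). The interferon-inducible GTPase gene Gbp4 (1.40, 1.19 to 1.66), the leukocyte adhesion gene Vcam1 (1.26, 1.08 to 1.47), the transcription factor gene Tal1 (1.56) and the tetraspanin gene Tspan12 (1.47) were higher among genes screened after the values were seen. Heat shock genes had a median of 0.13, with Hspa1b at 1.67 and Hspa1a at 1.53; it was -0.00 as a mean of each cell's CPM. Immediate early genes had a median of 0.13, with Nr4a1 at 1.30 and Jun at 1.18, and cytokine and NF-kB target genes one of 0.17.

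Cyp26b1, the gene of a retinoic acid-degrading enzyme, was lower in the endothelial-like cells of the drug library, at 0.577 (0.498 to 0.667). It had a UMI in 19.8% of noise-only and 11.4% of drug cells of the class against 0.460% and 0.751% of other cells, at class median depths of 1513.5 and 1121 UMIs. The fenestral diaphragm gene Plvap stood at 0.611, the mitochondrial anchoring protein gene Akap1 at 0.480, Lpcat1 at 0.523 and the kinesin gene Kif23 at 0.506, all screened after the values were seen. The fixed rule named the venular adhesion gene Selp (0.289, 0.172 to 0.470), the lymphatic chemokine gene Ccl21a (0.399), Fabp4 (0.202), Ttr (0.249) and S100a9 (0.370) as lower. In S100a9, 1 cell held 92.6% of the noise-only UMIs, and the ratio was 2.27 without the top cells. In Ttr, 1 cell held 73.5% of the drug UMIs, and the ratio was 0.0715 without the top cells. The top cells held 41.9% of the noise-only and 52.9% of the drug UMIs of Ccl21a, and 30.7% and 44.6% of those of Fabp4. It named Slc1a2 (5.45), Spp1 (3.05), Fbxo2 (2.80), Cxcl2 (5.66, with 44.5% of the drug UMIs in 1 cell) and Ccl5 (7.67, 45.3% in 1 cell) as higher. These 5, like Ttr and S100a9, had a UMI in a smaller share of endothelial-like than of other cells in both libraries, and Fbxo2 turned to 0.641 with cells of at least 1000 genes, 0.919 with at least 500 and 0.927 with a mitochondrial limit of 10%. Cluster 8 held the most endothelial-like cells of the noise-only library (541, against 521 in cluster 5) and cluster 5 the most of the drug library (1026, against 615 in cluster 8).

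In the epithelium-like cells, interferon response genes had a median log2 ratio of 0.19, with 4 of 20 higher and 1 lower; the antiviral tether gene Bst2 stood at 1.49, Ifi27l2a at 1.22 and the transcription factor gene Irf1 at 0.667. Growth factor genes had a median of -0.36 (6 of 11 lower), with Igf1 at 0.780 and Hgf at 0.598. Glycolysis and hypoxia genes had a median of -0.18, with the lactate dehydrogenase gene Ldha at 0.794, and heat shock genes one of 0.07, with Hspa1b at 1.46 and Dnajb1 at 1.30. Epyc, a proteoglycan gene of supporting cells, stood at 1.45 (1.37 to 1.54), Lum at 1.72, the cartilage gene Ucma at 2.29, the apolipoprotein gene Apoc1 at 2.02 and the carbonic anhydrase gene Car12 at 2.02. The GDNF receptor gene Gfra1 stood at 0.706 (0.638 to 0.780), the glutathione transferase gene Gstm2 at 0.595, Nme5 at 0.427, Rufy1 at 0.563 and Tmc6 at 0.489. These 10 were screened after the values were seen. The class held cluster 7, with 514 noise-only and 731 drug cells, cluster 18, with 364 and 360, and cluster 25, with 167 and 227, and with the noise-only cluster weights Epyc stood at 1.22, Lum at 1.45 and Gfra1 at 0.837. The fibrocyte-like cluster 15 held 52.8% of the drug Ucma UMIs. The fixed rule named S100a8 (13.8), S100a9 (10.2), Slc1a2 (7.61), Slc4a11 (6.52) and the calcification inhibitor gene Mgp (3.58) as higher, each with a UMI in a smaller share of epithelium-like than of other cells in both libraries. In 1 cell lay 33.9% of the drug S100a8, 40.0% of the drug S100a9 and 63.2% of the noise-only Slc4a11 UMIs, and the Slc4a11 ratio was 14.6 without the top cells. It named Wfdc18 (0.122), Ibsp (0.0850), Bglap (0.0911), Prol1 (0.137) and Ttr (0.392) as lower, where 1 cell held 42.8% of the noise-only Wfdc18 UMIs, 78.1% for Ibsp, 57.7% for Bglap and 74.5% for Prol1. With predicted doublets kept, the interferon median was 0.01, S100a8 turned to 0.542, S100a9 to 0.412, Prol1 to 1.53 and Wfdc18 to 1.16, and with cells of at least 500 genes Wfdc18 turned to 6.49.

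In macrophage-like cells, chaperone genes were higher and cell cycle genes lower in the drug library. Of 13 heat shock genes, 6 were higher and none lower, at a median log2 ratio of 0.30; Hspa1b, an inducible HSP70 gene, was 3.04-fold higher (2.19 to 4.26) and Hspa1a 2.03-fold higher. Of 18 cell cycle genes, 10 were lower and 1 higher, at a median of -0.37, with the replication genes Mcm2 at 0.401 and Pcna at 0.642. Immediate early genes had a median of 0.24, with Jun at 1.29 and Egr1 at 1.28, and MHC class I genes one of -0.36 (6 of 11 lower), with Psmb8 at 0.745 and Psmb9 at 0.733. With cells of at least 1000 genes the heat shock median was 0.02, the cell cycle median -0.06 and the immediate early median -0.11.

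The chemokine genes Ccl12, Cxcl2, Ccl4, Ccl3 and Ccl7 were among the leading genes of the macrophage-like cluster 16, which held 322 noise-only and 498 drug cells; clusters 23 and 34 held 259 and 208, and 106 and 108. Cytokine genes showed no member higher in the class. Genes screened after the values were seen that were lower included the thymidine kinase gene Tk1 (0.427, 0.248 to 0.712), Mcm7 (0.472), Cxcl10 (0.619, 0.535 to 0.714), Pmf1 (0.477) and AA467197 (0.425). Those higher were Dtx3l (2.34), the transcription factor gene Nfil3 (1.85), the hyaluronan receptor gene Lyve1 (1.91), the prostaglandin receptor gene Ptger4 (1.77) and the lectin gene Clec4n (1.83). The last 3 turned to 0.503, 0.866 and 0.845 at a clustering resolution of 0.5, where the class held 351 noise-only and 312 drug cells against 687 and 814. The fixed rule named Bglap2, an osteocalcin gene, (at least 82.4-fold, 264 and 0 UMIs), Retnla (225 and 1 UMIs, ratio 0.00475, 0.000120 to 0.0267), Bglap (0.0218), Ttr (0.0200) and Bpifa1 as lower. In 1 noise-only cell lay 42.0% of the Bglap2, 52.4% of the Retnla, 42.9% of the Bglap and 97.0% of the Bpifa1 UMIs, and over all cells the osteoblast-like cluster 14 held 95.7% of the noise-only Bglap2 and 96.3% of the noise-only Bglap UMIs. It named as higher Hspa1b, Otos (4.09, 35.8% of the drug UMIs in 1 cell), Car2 (3.80), Dnase1 (67.2% in 1 cell) and Col3a1 (78.0% in 1 cell). The last 3 had a UMI in a smaller share of macrophage-like than of other cells in both libraries. Bpifa1 lay above 1 in 6 settings (1.37 to 1.62), Dnase1 turned to 0.466 with doublets kept and 0.704 at a resolution of 0.5, and Col3a1 turned to 0.961 as a mean of each cell's CPM.

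In pericyte-like cells, interferon genes had a median log2 ratio of -0.19 at percentile 2.66, with 9 of 22 lower and 3 higher; Ifit3 stood at 0.497 and Cxcl10 at 0.327, with 45.9% of its noise-only UMIs in 1 cell. The heat shock genes Hspa1b and Hspa1a stood at 1.86 (1.38 to 2.53) and 1.47 (1.28 to 1.69). The lymphoid chemokine gene Ccl19 was 4.46-fold higher (3.02 to 6.80), the prostaglandin synthase gene Ptgds 2.67-fold higher (2.49 to 2.85), Slc1a2 6.88-fold, S100a9 7.96-fold and S100a8 7.24-fold higher (67.0% and 51.7% of the drug UMIs in 1 cell). All but Ccl19 had a UMI in a smaller share of pericyte-like than of other cells in both libraries, Ptgds in 48.6% against 57.6% in the noise-only and 73.4% against 79.2% in the drug library. The insulin-like growth factor binding protein gene Igfbp5 (0.490), Spp1 (0.556), Glg1 (0.485) and Ttr (0.0381) were lower. Screening after the values were seen added Zic1 (2.11), the vessel-stabilising ligand gene Angpt1 (2.05) and the contractile protein gene Tagln (1.40) as higher. It added the GTPase gene Rem1 (0.633), Ccdc3 (0.572), Mgp (0.80), the endothelin receptor gene Ednrb (0.687) and Pou3f4 (0.698, 0.567 to 0.858) as lower. Complement genes had a median of 0.48, with no single member's interval excluding 1. The setting of at least 1000 genes left 24 noise-only and 29 drug pericyte-like cells, in which Angpt1 turned to 0.554, Rem1 to 1.66, Spp1 to 1.18, Tagln to 0.853 and S100a8 to 0.739.

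**Figure D2:**
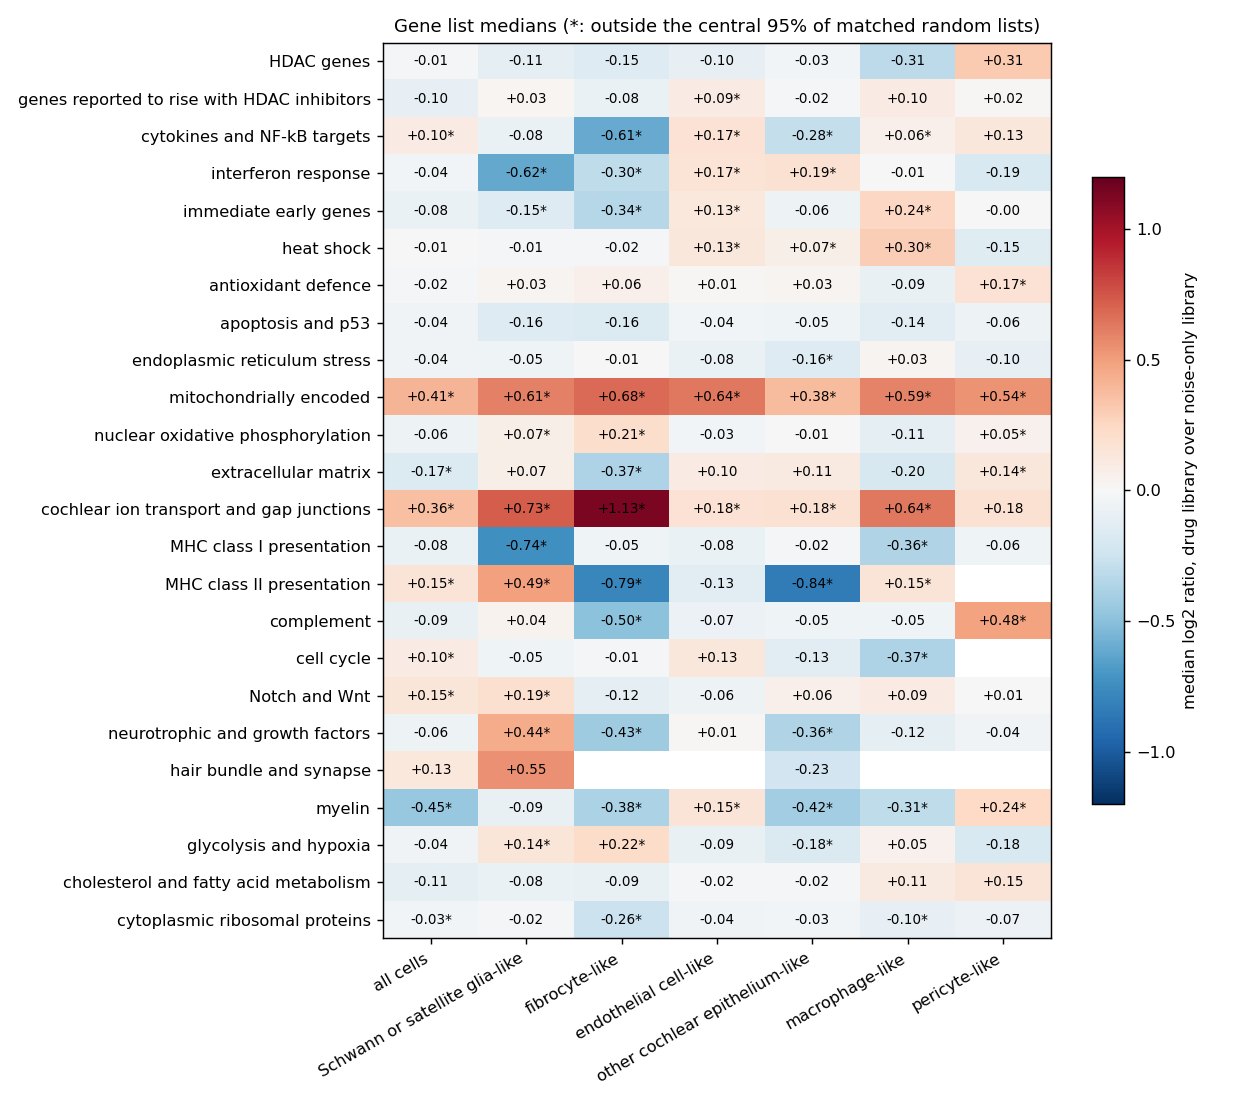
Median log2 ratio (drug over noise-only) of each fixed gene list in all cells and in the 6 main cell classes; marked cells lie outside the central 95% of 10000 matched random lists. The mitochondrially encoded list is above that range in every column, from 0.38 in the epithelium-like class to 0.68 in the fibrocyte-like class, and the interferon list is at -0.62 in the Schwann-like and 0.17 in the endothelial-like class.

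**Figure D3:**
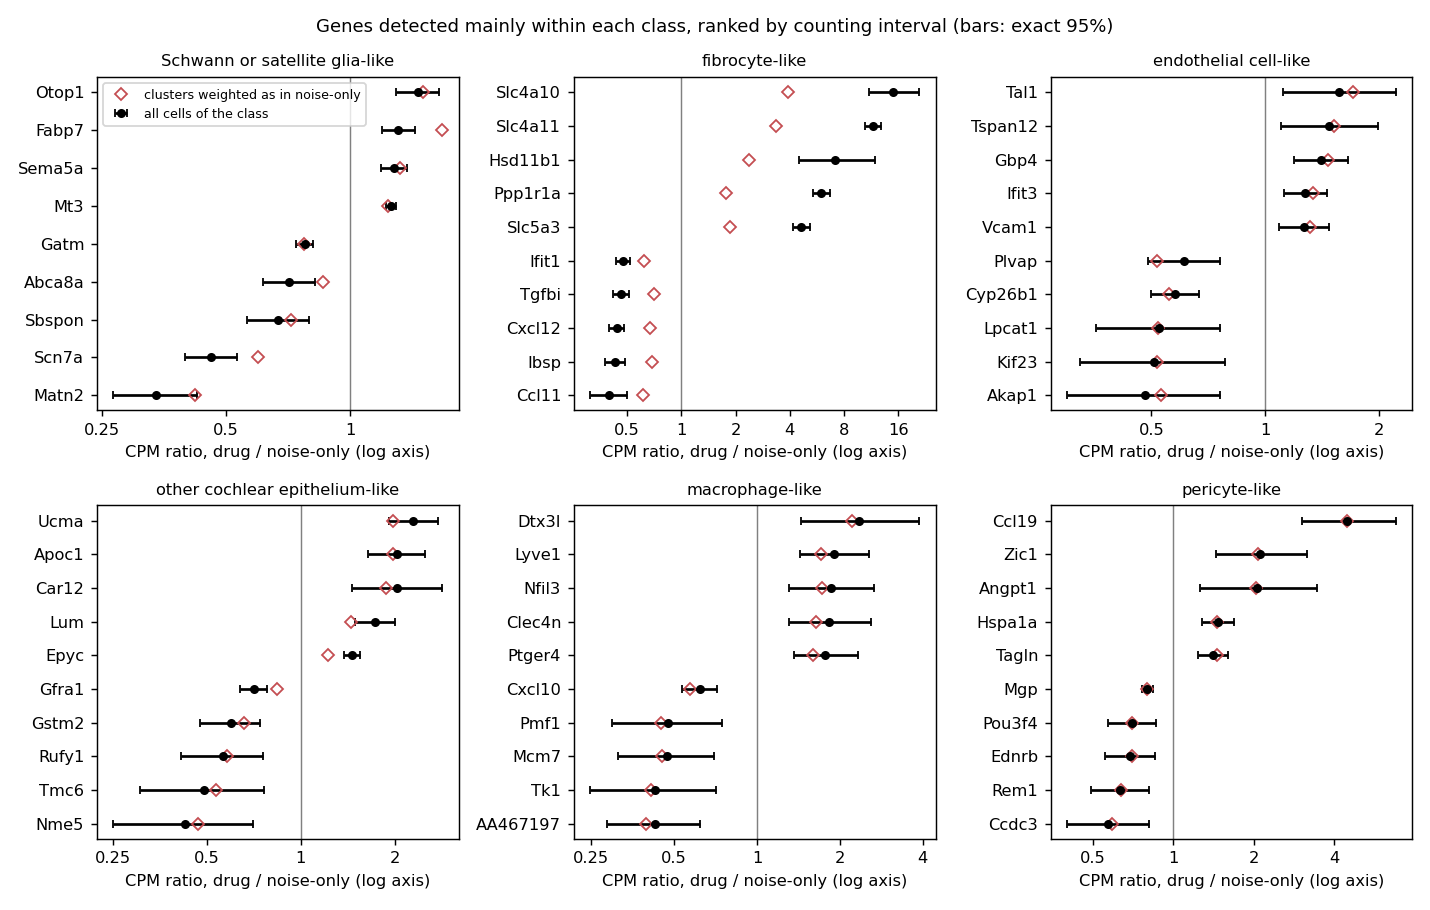
CPM ratio (drug over noise-only, log axis) of genes screened after the values were seen in each main cell class; filled points are all cells of the class with exact 95% counting intervals, and open diamonds weight clusters as in the noise-only library. Slc4a11 in fibrocyte-like cells stands at 11.6 and at 3.36 with those weights, and Scn7a in Schwann-like cells at 0.460.

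Across the 6 main classes, 21 genes were at least 1.5-fold higher and 2 at most 0.67-fold as high in 5 or more of them. By median ratio the first 10 of the higher genes were the water channel gene Aqp4 (9.55), Slc4a11 (6.61), Slc1a2 (4.97), Aldoc (2.91), Scrg1 (2.85), Ppp1r1a (2.63), the calcium buffer gene Pvalb (2.45), the platelet-activating factor hydrolase gene Pla2g7 (2.42), the potassium channel gene Kcnj10 (2.40) and Otos (2.34). The lower genes were Ttr (0.0583) and the autotaxin gene Enpp2 (0.485). Aqp4 and Slc1a2 were among the leading genes of the unnamed cluster 32, which had 34 noise-only and 234 drug cells (share ratio 6.22, 4.33 to 9.20) and held 34.7% of the drug UMIs of Slc1a2. Other leading genes of cluster 32 included Slc7a10, Ntsr2, Gja1 and Slc4a4. The 28 fixed cell types held no astrocyte, so the naming rule could not give that name. The tissue that cluster 32 came from was not determined. Ttr had a UMI in 19.8% to 32.3% of the cells of each main class in the noise-only library and in 0.614% to 10.8% in the drug library, where the epithelium-like class had 10.8% and the others at most 1.28%, including classes such as macrophage-like and endothelial-like cells that should lack it. After thinning to 1000 UMIs, which left out 7245 noise-only and 7798 drug cells, the ranges were 11.6% to 21.7% and 0.539% to 10.99%. Otos, a fibrocyte gene, had a UMI in 3.05% to 8.64% and 7.62% to 27.1% (thinned, 1.71% to 8.42% and 5.24% to 28.1%); in the drug library the main classes other than fibrocyte-like had at most 9.41%. RNA free in the droplets was not measured, and the ratios of the genes named across classes and of S100a8 and S100a9 in classes that should lack them are not read as expression of those classes.

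**Figure D4:**
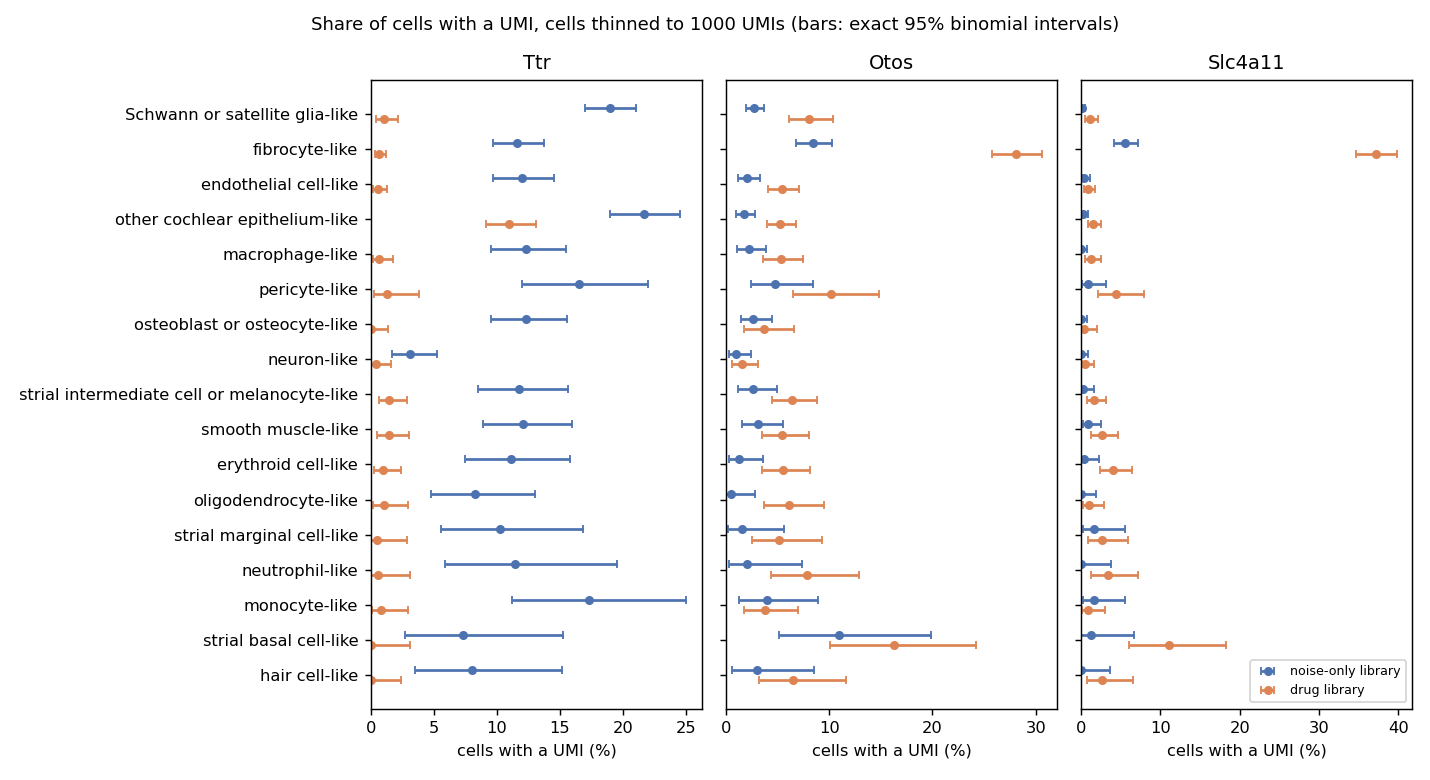
Share of cells (percent) with at least 1 UMI of Ttr, Otos and Slc4a11 in each of the 17 compared cell classes after thinning each cell to 1000 UMIs, noise-only against drug library, with exact 95% binomial intervals. Ttr spans 11.6% to 21.7% of noise-only cells and 0.539% to 10.99% of drug cells over the 6 main classes.

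By the GENCODE M21 annotation of GRCm38, Ttr (ENSMUSG00000061808) spans chromosome 18 from 20665280 to 20674321, Slc4a11 (ENSMUSG00000074796) chromosome 2 from 130684113 to 130697519 and Glycam1 (ENSMUSG00000022491) chromosome 15 from 103562759 to 103565081. Cxcl10 (ENSMUSG00000034855) spans chromosome 5 from 92346638 to 92348889, Psmb8 (ENSMUSG00000024338) chromosome 17 from 34197721 to 34201454 and Hspa1b (ENSMUSG00000090877) chromosome 17 from 34956436 to 34959238. Tac1 (ENSMUSG00000061762) spans chromosome 6 from 7554879 to 7565834, Cyp26b1 (ENSMUSG00000063415) chromosome 6 from 84571414 to 84593908, Matn2 (ENSMUSG00000022324) chromosome 15 from 34306677 to 34436273 and Saa1 (ENSMUSG00000074115) chromosome 7 from 46740497 to 46742980.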

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

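Settings added after seeing the data were the noise-only cluster weights, the omission of cluster 15, of clusters 35, 40 and 41, of the cell with the most UMIs of a gene, and of list members held by 1 cell or found in a smaller share of the class than of other cells. Of the 54 values of the 6 share ratios under other settings, 38 stayed within the counting interval, 14 moved and 2 reversed; the Schwann-like ratio ran from 0.413 to 0.559. A list median was called moved where it left a band centred on its main value and as wide as its random range. The 13 list medians picked by hand as answering a comparison kept their direction where they lay outside their random range. Of their 244 values, 212 stayed within that band and 32 moved. Interferon genes in Schwann-like cells ran from -0.73 to -0.20 and MHC class I genes from -0.81 to -0.089. Of the other 256 list medians rerun, 4193 of 4586 values stayed, 330 moved and 63 reversed, and of the 136 gene ratios, 1842 of 2226 values stayed, 346 moved and 38 reversed. With 5 expression bins in place of 20, 13 of 13 percentiles stayed on their side of the central 95% and 246 of the other 256 did. List medians were rerun for all cells, the 6 main classes and the hair cell-, neuron-, monocyte-, neutrophil- and osteoblast-like classes, and not for the other 6 classes. The monocyte-like class was not formed under 4 settings, and the neutrophil-like class not with at least 1000 genes per cell. In these scopes no scaling moved every log2 ratio by more than 0.097, except that TMM moved it by 0.21 and median of ratios by 0.22 in neutrophil-like cells. No paired analysis was possible because each group is 1 pooled library, so ears of the same mouse cannot be matched. Depth limits the gene ratios: in simulated pairs of macrophage-like sums, intervals excluded 1 for 68.9% of genes with a true 1.5-fold difference and for 92.3% with a 2-fold one. For the values that follow, the cause was not tested, except that weighting clusters by construction removes differences in cluster make-up. Equal class weights likewise remove differences in class shares. Leaving out cluster 15 removes that cluster alone, and clusters 2 and 10, with share ratios of 0.992 and 1.53, still differed in make-up.

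With a mitochondrial limit of 10 percent, the share ratio was 0.423 for Schwann-like cells. There, median log2 ratios were, in neutrophil-like cells -0.088 for antioxidant genes, 0.61 for ribosomal protein genes, 0.47 for endoplasmic reticulum stress genes and -0.65 for matrix genes, in all cells 0.32 for mitochondrially encoded transcripts and in pericyte-like cells -0.069 for myelin genes. Gene ratios were 1.44 for Bpifa1 in macrophage-like cells and 0.927 for Fbxo2 in endothelial-like cells. Without a mitochondrial limit, the median log2 ratio was -0.013 for myelin genes in pericyte-like cells. The gene ratio was 1.51 for Bpifa1 in macrophage-like cells. With at least 500 genes per cell, the share ratio was 0.413 for Schwann-like, 1.29 for endothelial-like, 1.34 for fibrocyte-like, 1.253 for macrophage-like and 1.10 for pericyte-like cells. There, median log2 ratios were, in epithelium-like cells 0.12 for MHC class II genes and 0.23 for cytokines, in neutrophil-like cells -0.086 for antioxidant genes, -0.13 for cytokines, -0.16 for HDAC inhibitor-responsive genes and -0.047 for immediate early genes, in Schwann-like cells -0.73 for interferon genes and in pericyte-like cells -0.14 for myelin genes. Gene ratios were 0.834 for Fabp7 in Schwann-like cells, 0.919 for Fbxo2 in endothelial-like cells and 6.49 for Wfdc18 in epithelium-like cells. With at least 1000 genes per cell, the share ratio was 0.443 for Schwann-like, 0.972 for endothelial-like, 1.35 for fibrocyte-like, 0.818 for macrophage-like, 0.986 for epithelium-like and 1.23 for pericyte-like cells. There, median log2 ratios were, in Schwann-like cells -0.089 for MHC class I genes, 0.10 for immediate early genes and -0.20 for interferon genes, in all cells -0.034 for MHC class II genes, -0.18 for cytokines, 0.0031 for HDAC inhibitor-responsive genes and 0.25 for mitochondrially encoded transcripts, in macrophage-like cells -0.30 for MHC class II genes, -0.056 for cell cycle genes, -0.31 for cytokines, 0.025 for heat shock genes and -0.11 for immediate early genes, in pericyte-like cells -0.19 for antioxidant genes, -0.41 for matrix genes and -0.33 for nuclear oxidative phosphorylation genes, in fibrocyte-like cells 0.82 for ion transport, in osteoblast-like cells -0.14 for ribosomal protein genes, -0.10 for glycolysis genes and 0.20 for immediate early genes and in endothelial-like cells 0.28 for interferon genes. Gene ratios were 0.554 for Angpt1, 1.66 for Rem1, 0.739 for S100a8, 1.18 for Spp1 and 0.853 for Tagln in pericyte-like cells, 0.988 for Fabp7, 2.25 for Ifi47, 1.01 for Matn2, 0.919 for Otos and 1.06 for Ttr in Schwann-like cells, 0.641 for Fbxo2 in endothelial-like cells and 0.858 for Wfdc18 in fibrocyte-like cells. With predicted doublets kept, the share ratio was 0.503 for Schwann-like cells. There, median log2 ratios were, in macrophage-like cells -0.051 for MHC class II genes and -0.075 for cytokines, in neutrophil-like cells -0.069 for antioxidant genes, in epithelium-like cells 0.22 for cytokines and 0.011 for interferon genes, in hair cell-like cells -1.04 for immediate early genes, in endothelial-like cells 0.10 for interferon genes and in pericyte-like cells -0.061 for myelin genes. Gene ratios were 0.466 for Dnase1 in macrophage-like cells, 0.974 for Fabp7 in Schwann-like cells and 1.53 for Prol1, 0.542 for S100a8, 0.412 for S100a9 and 1.16 for Wfdc18 in epithelium-like cells. At clustering resolution 0.5, the share ratio was 1.37 for fibrocyte-like and 0.804 for macrophage-like cells. There, median log2 ratios were, in macrophage-like cells -0.48 for MHC class II genes, -0.55 for cell cycle genes, -0.064 for cytokines, 0.63 for heat shock genes and 0.10 for myelin genes, in fibrocyte-like cells 0.81 for ion transport and -0.046 for glycolysis genes and in hair cell-like cells -0.49 for immediate early genes. Gene ratios were 1.61 for Bpifa1, 0.845 for Clec4n, 0.704 for Dnase1, 0.503 for Lyve1 and 0.866 for Ptger4 in macrophage-like cells and 0.956 for Fabp7 in Schwann-like cells. At clustering resolution 2.0, the share ratio was 2.39 for fibrocyte-like cells. There, median log2 ratios were, in fibrocyte-like cells 1.39 for ion transport and in osteoblast-like cells -0.22 for ribosomal protein genes, -0.047 for endoplasmic reticulum stress genes, -0.12 for glycolysis genes and 0.12 for immediate early genes. Gene ratios were 1.51 for Bpifa1 in macrophage-like cells and 5.62 for Lcn2 in fibrocyte-like cells. With genes scaled within library, median log2 ratios were, in epithelium-like cells 0.12 for cytokines and in endothelial-like cells -0.23 for myelin genes. Gene ratios were 1.62 for Bpifa1 in macrophage-like cells and 0.949 for Fabp7 in Schwann-like cells. With TMM scaling, the median log2 ratio was 0.0016 for ribosomal protein genes in all cells. With mitochondrial, ribosomal and haemoglobin genes out of the total, median log2 ratios were, in neutrophil-like cells -0.036 for antioxidant genes and in all cells 0.0032 for ribosomal protein genes. As a mean of each cell's CPM, median log2 ratios were, in macrophage-like cells -0.56 for cell cycle genes, in fibrocyte-like cells 0.88 for ion transport, in osteoblast-like cells -0.045 for cytokines, in epithelium-like cells 0.048 for cytokines, in neutrophil-like cells 0.0068 for endoplasmic reticulum stress genes, in endothelial-like cells -0.0037 for heat shock genes and in hair cell-like cells -0.69 for immediate early genes. The gene ratio was 0.961 for Col3a1 in macrophage-like cells. With cells thinned to 1000 UMIs, median log2 ratios were, in neutrophil-like cells -0.15 for antioxidant genes and -0.21 for HDAC inhibitor-responsive genes, in fibrocyte-like cells 0.84 for ion transport, in hair cell-like cells -0.76 for immediate early genes, in epithelium-like cells 0.32 for interferon genes and in pericyte-like cells -0.0088 for nuclear oxidative phosphorylation genes. With list members of at least 1 UMI, median log2 ratios were, in neutrophil-like cells 0.18 for complement genes and in pericyte-like cells -0.0055 for matrix genes. With list members of at least 100 UMIs, median log2 ratios were, in fibrocyte-like cells 0.77 for ion transport and in monocyte-like cells 0.13 for HDAC inhibitor-responsive genes. With the 6 main classes weighted equally, median log2 ratios were, in all cells -0.31 for cell cycle genes, -0.026 for cytokines, 0.045 for HDAC inhibitor-responsive genes and 0.58 for mitochondrially encoded transcripts. With clusters weighted as in the noise-only library, median log2 ratios were, in fibrocyte-like cells 0.33 for ion transport, -0.0016 for glycolysis genes and 0.030 for immediate early genes and in macrophage-like cells -0.081 for cytokines. Without cluster 15, median log2 ratios were, in fibrocyte-like cells 0.20 for ion transport, -0.066 for glycolysis genes, 0.053 for immediate early genes and -0.017 for nuclear oxidative phosphorylation genes. The gene ratio was 0.701 for Slc4a10 in fibrocyte-like cells. Without clusters 35, 40 and 41, the median log2 ratio was -0.0020 for myelin genes in pericyte-like cells. Without the cell holding the most UMIs of a gene, the median log2 ratio was -1.06 for immediate early genes in hair cell-like cells. Gene ratios were 1.37 for Bpifa1 in macrophage-like cells and 2.27 for S100a9 in endothelial-like cells. Without list members held by 1 cell or in a smaller share of the class than of other cells, median log2 ratios were, in neutrophil-like cells -0.72 for antioxidant genes, in fibrocyte-like cells 0.13 for ion transport and in epithelium-like cells 0.29 for interferon genes.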

Other observations

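Of the tests below, the 3 chosen only after the result was seen were the cluster weightings in Schwann-like and in fibrocyte-like cells and the test of nuclear oxidative phosphorylation genes. The genes named in the next 2 paragraphs are the list members furthest apart in classes outside the main comparisons, and those lists were picked for their values.

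Hair cell-like cells of the drug library (161 against 103 noise-only cells) had lower immediate early genes, with 15 of 18 lower, 1 higher and a median log2 ratio of -1.27 where random lists ran from -0.22 to 0.15; the median was -0.49 at a clustering resolution of 0.5, -0.69 as a mean of each cell's CPM and -0.76 after thinning to 1000 UMIs. Ier2 stood at 0.248 (95% counting interval 0.182 to 0.333) and the nuclear receptor gene Nr4a1 at 0.185, although 1 noise-only cell held 28.8% of the Ier2 and 47.9% of the Nr4a1 UMIs. Genes of the hair bundle and the ribbon synapse had a median of -0.07 at percentile 44.5. Lhfpl5, a subunit gene of the mechanotransduction complex, stood at 1.60 (1.23 to 2.11) and Otof, the gene of the synaptic calcium sensor otoferlin, at 1.18 (1.01 to 1.39), while the scaffold gene Ush1c stood at 0.700. In neuron-like cells, cholesterol and fatty acid genes had a median of 0.24, with the sterol regulator gene Srebf2 at 1.82 and the squalene epoxidase gene Sqle at 1.65. Genes reported to rise with HDAC inhibitors had a median of -0.20 there, at percentile 0.040 (-0.088 after thinning to 1000 UMIs), with none of 14 higher and Cdkn1a at 0.724 (0.608 to 0.861).

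The monocyte-like class was 1 cluster (26), whose leading genes included the MHC class II genes H2-Ab1, H2-Eb1 and H2-Aa and their partner Cd74 beside the monocyte markers Plac8, Ccr2 and Ly6c2, and dendritic or other antigen-presenting cells in it were not told apart from monocytes. Its cells in the drug library had lower interferon genes (13 of 17 lower, median log2 ratio -0.42) and lower MHC class II genes (6 of 7, median -0.79), such as Cxcl10 (0.421) and the invariant chain gene Cd74 (0.577). Their cytokine and NF-kB target genes had a median of 0.52, with the neutrophil-attracting chemokine gene Cxcl2 at 2.71 (2.41 to 3.05). The cytokine median was 0.15 without a mitochondrial limit and 0.24 at a clustering resolution of 2.0, and the class was not formed under 4 settings. In neutrophil-like cells the medians depended on the filters: the cytokine median of 1.09 (Ccl4 at 10.5, 7.13 to 16.1) turned to -0.13 and the immediate early median of 0.73 to -0.047 with cells of at least 500 genes, and the ribosomal protein median of -1.0 turned to 0.61 with a mitochondrial limit of 10%. Osteoblast-like cells had MHC class I genes at a median of -0.48 (-0.96 with cells of at least 1000 genes and -0.15 as a mean of each cell's CPM), with H2-D1 at 0.513 and H2-K1 at 0.511, and endoplasmic reticulum stress genes at 0.23, with the chaperone genes Pdia4 at 1.90 (1.52 to 2.37) and Hsp90b1 at 1.43; that median turned to -0.047 at a clustering resolution of 2.0, where the class held 413 cells against 870.

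Interferon and MHC class I genes were lower in the Schwann-like cells of the drug library. The values argue against a shift between clusters of the class as the whole cause for interferon genes. Their median was -0.55 with noise-only cluster weights and -0.62 without them. The random range of -0.14 to 0.05 was that of unweighted ratios, and no random lists were drawn from weighted ones. After thinning to 1000 UMIs the interferon median was -0.71 (random range -0.17 to 0.14). Thinning kept 1483 of 6619 noise-only and 661 of 3989 drug cells of the class. Ratios of summed UMIs scaled to their totals are not shifted by an even loss of depth. This test therefore could not decide whether lower depth per cell was a cause. Less free RNA of these genes in the drug droplets cannot be told apart from lower expression: the Schwann-like cells lost 1.10 UMIs per cell of both lists with drug cells scaled to the mean UMIs per noise-only cell of the class, and the other 16 classes lost a median of -0.68 (a gain), but their quartiles ran from -0.92 to 0.91 and 6 of them lost UMIs. An effect of the drug stays open and untested, as does any other difference between single pools, and the smaller medians with cells of at least 1000 genes (-0.20 for interferon genes) leave the size uncertain.

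Mitochondrially encoded transcripts lay above the random range in 16 of 17 classes. Per cell, mitochondrial UMIs had a median log2 ratio of 0.092 over the classes (range -0.25 to 0.40) and were higher in 11 of 17. Other UMIs had one of -0.35 and were lower in 17 of 17, so loss of other RNA from damaged cells is a candidate explanation. Loss alone would not give the higher mitochondrial UMIs per cell in Schwann-like and fibrocyte-like cells, at 0.40 in each. UMIs per cell also follow library depth, so these values do not show a loss. Median UMIs per class had been seen before this test was set. Cells above 10 percent mitochondrial UMIs were not the whole cause, as the median over all cells was 0.32 with that limit. The test cannot speak to cells of raised percent below the limit. Analysed cells had medians of 4.88% in the noise-only and 6.69% in the drug library. Over all cells, the nuclear oxidative phosphorylation genes argue against a joint rise with the mitochondrial ones, as their median was -0.062. In the classes it lay between -0.20 and 0.21. The highest was in fibrocyte-like cells (-0.017 without cluster 15), where a joint rise was not excluded. Whether the drug or the handling of 1 of the pools lies behind the difference was not tested.

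Cochlear ion transport genes were higher in the fibrocyte-like cells of the drug library. A shift between clusters may account for much of it: the median went from 1.13 to 0.33 with noise-only cluster weights (random range -0.28 to 0.11) to 0.20 without cluster 15, and to 0.13 over the 7 of 13 members left without those with over 20% of their UMIs in 1 cell or found in a smaller share of the class than of other cells. The random range of -0.28 to 0.11 was that of unweighted ratios, and no random lists were drawn from weighted ones. The weighted median stayed above that range, and a shift between clusters and a difference within clusters cannot be told apart. Outside cluster 15, free RNA is a candidate source of the Slc4a11 difference, as clusters 2 and 10 gained 35.6 Slc4a11 UMIs per 1000 cells against a median gain of 39.2 in the other 16 classes, a ratio of 0.91. Whether cluster 15, with 121 noise-only and 719 drug cells, differed through the drug or through the part of the lateral wall dissected stays open and was not tested.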
